A study of Mus musculus with 3 samples.

How the data were processed

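PolyA-selected RNA of naive CD4 T cells from 1 mouse was sequenced in 3 technical libraries; per the labels, RNA was sheared by sonication (Covaris) and the size range was 100 to 300. All libraries form 1 group with 1 biological replicate, and the technical replicate number in the labels names each library. Per the text that accompanies the deposited files, the assembly was mm10 and the annotation GENCODE M21 for the gene and transcript tables and GENCODE M4 for a further count table. The aligner, the counting tool and their versions are not given in the sources used here, nor is whether counting used strand.

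For each library the authors deposited a gene table and a transcript table with expected counts, which are estimated reads per gene that need not be whole, and the same quantity as a posterior mean. TPM, per the file headers, were deposited in those tables as maximum-likelihood and posterior mean estimates, and the deposited FPKM were not used here. Isoform percent, the percent of a gene's TPM given to each transcript, was taken from the deposited transcript tables. Lengths were deposited beside them, and length minus effective length was 49 for genes. Whole-number counts per gene on the older M4 annotation were deposited in a table of 22457 genes for each library and were used here only for alternatives and for the closing tests. TPM were scaled by the authors over all entries, which besides 55536 genes include 26248 short entries with numeric identifiers, 96 ERCC spike-in entries and a phiX entry. The entries that name no gene were left out of library sizes and tests; they held 0.247%, 0.200% and 0.325% of expected counts in libraries 1, 2 and 3. Symbols were found for 55450 of the gene identifiers, and all of the identifiers occur in the GENCODE M21 annotation used for coordinates and biotypes. Where a symbol has several entries, as Aldoa does, their values were summed.

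Totals of expected counts were 14837442, 18207118 and 17505621. A count of 0 in a library allows up to 3 counts. On a transcript with a length of 1 kilobase, 3 counts correspond to 0.367, 0.283 and 0.309 TPM in libraries 1, 2 and 3. Reads carry no molecular identifiers, so such limits and all intervals cover counting error only.

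Gene lists, gene pairs, isoform genes and the rule for named genes were fixed before the data were examined. A gene was called detected at TPM of at least 1 in every library. For each of 31 lists the median over members of mean TPM, the SD of the per-library medians and the percentile of the median among 10000 random lists of protein-coding genes of the same size were computed; the percentile describes these libraries and is no test. The text names for each list the 4 members of highest mean TPM, all members of the 22 pairs, the 10 genes of highest TPM, the most abundant transcript of 16 genes, and the 10 genes with the largest ratio of highest to lowest TMM-scaled count among those past the threshold with a mean of at least 100 counts. Some genes that this rule names are not reported here, though they count in the list, pair and isoform totals. The summary counts of pairs with the first gene higher and of isoform shares of at least 50% were defined after seeing the data. A gene with 0 counts in a library has an unlimited ratio and ranks first. Pair ratios used a pseudocount of 0.1 and list differences one of 1 on the log2 scale; pairs were also given as pooled ratios with exact Clopper-Pearson 95% intervals.

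Expected counts were rounded to whole numbers before any count test. Library sizes were scaled by TMM (edgeR 4.0.16, R 4.3.3) over genes with a mean of at least 10 counts. Differences between libraries were tested per gene by chi-square homogeneity with Benjamini-Hochberg adjustment (scipy 1.17.1), and the technical coefficient of variation is the square root of edgeR's common dispersion with an intercept only. With 1 group there was no comparison between groups to test, and no p-value across conditions is given.

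The test was tested on simulated libraries drawn with counting noise only for 12938 genes at the real depths. Of 50 genes changed in library 2 at each size, it called 21 at 1.2-fold, 30 at 1.5-fold, 42 at 2-fold and 50 at 4-fold, and 6 of 12739 unchanged genes. For a simulated coefficient of variation of 12%, over 12925 genes, edgeR's common dispersion gave 12.0% and DESeq2's median gene-wise dispersion 8.58%. For 5%, over 12961 genes, edgeR gave 4.98%. It gave 7.79% over 12945 genes when 200 of them were changed in library 2, so a few strongly differing genes raise this value. DESeq2's median at 5% was 0.01% with no gene changed and 1.68% with the changed genes, far below the truth.

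Alternatives covered library totals and DESeq2 size factors (1.42.0) in place of TMM, other count and TPM minimums, pseudocounts of 1 and 0.01 for pairs and 0.1 for lists, posterior mean estimates, expected counts with no length correction (pseudocount 0.5 for pairs), TPM rescaled over protein-coding genes without ribosomal protein and mitochondrial genes, a deviance test, and each library left out in turn. Use of the counts on the older annotation was added after seeing the data. Figures were drawn with matplotlib 3.10.9.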

Results

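RNA was measured by polyA-selected sequencing in naive thymus-derived CD4 αβ T cells of 1 male mouse aged 5 months, of the B6.SJL strain, a C57BL/6 line that carries the Ptprc allele known as CD45.1. Naive CD4 T cells are helper T cells that have left the thymus and have not yet met their antigen. The group held 3 technical libraries of 1 biological replicate, so every SD below is the spread between technical libraries (n = 3) and no comparison between conditions or animals can be made. Totals of expected counts were 14837442, 18207118 and 17505621 in libraries 1, 2 and 3. Levels are given in TPM, the deposited length-scaled transcript abundance, as mean ± SD over the 3 libraries unless another quantity is named, and positions are those of the mouse assembly GRCm38 (mm10) in the GENCODE M21 annotation. Intervals and detection limits cover counting error only.

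Among the 10 genes of highest TPM, H2-K1 (chromosome 17, 33996017 to 34000347), a classical MHC class I heavy chain, stood at 9410.1 ± 218 and H2-D1, another such chain, at 5063 ± 373. Tmsb4x and Tmsb10, which encode actin-binding thymosins, had 8845 ± 352 and 4768 ± 137, the ribosomal protein gene Rps19 had 5508 ± 375, mt-Co3, a mitochondrial gene of the respiratory chain, had 6236 ± 666, and Vps37b, a component of the endosomal ESCRT-I complex, had 5682 ± 806. Other entries were Gm37376 at 6549 ± 761 and the ribosomal RNA entry CT010467.1, which had 2942, 10734 and 2579 TPM in libraries 1, 2 and 3. Gm37376 (chromosome 19, 5801941 to 5802393) lies within Malat1 on the opposite strand, so its reads and those of the noncoding RNA Malat1 cannot be told apart where the counting did not use strand. The same limit holds for Vps37b, which overlaps Hip1r on the opposite strand, and mt-Co3 overlaps mt-Atp6. H2-K1 and H2-D1 belong to a family of similar genes, and thymosin and ribosomal protein genes have processed copies, so their values are uncertain to the extent that reads were shared.

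In all, 11902 genes reached 1 TPM in every library, of which 9823 were among the 22028 annotated protein-coding genes. Of these genes, 1809 reached 100 TPM in every library. The number at 1 TPM or more in a single library was 13084 ± 112. The posterior mean estimates that the files also give raise the levels of genes with few reads, and with them 18019 genes reached 1 TPM in every library. The 10 highest genes held 6.35% ± 0.410 of TPM and the 100 highest 24.99% ± 1.76. Protein-coding genes held 87.3% ± 1.76 of TPM, ribosomal protein genes 7.75% ± 1.76, the 37 mitochondrially encoded genes 3.22% ± 0.345 and pseudogenes 5.17% ± 0.816. Pseudogene values are uncertain because such entries share reads with their parent genes. Constant-region genes of the T cell receptor held 0.611% ± 0.0311 and variable-segment genes 0.375% ± 0.0225 of TPM, while long noncoding biotypes together held 1.96% ± 0.0753 and histone genes 0.0392% ± 0.000945. Ribosomal RNA entries took 0.299%, 1.08% and 0.262% of TPM in libraries 1, 2 and 3. Library 2 was also the highest for ribosomal protein genes, at 9.77% of TPM against 6.89% and 6.59% in libraries 1 and 3, for mitochondrially encoded genes, at 3.60% against 2.94% and 3.12%, and for pseudogenes, at 6.11% against 4.71% and 4.68%.

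Genes of the naive state stood far above genes of effector and memory T cells. The labels call these cells naive, and the question was at what level each gene list was present. All 17 members of the naive and quiescence list were detected at 1 TPM or more in every library. The list median was 884 ± 58.9 TPM, above all of the random protein-coding lists of the same size (percentile 100). Random lists were drawn from all 22028 protein-coding genes, of which 9823 were detected. The reference gene and glycolysis lists also reached percentile 100, so this percentile does not set the naive list apart. Ccr7 (chromosome 11, 99144196 to 99155077), the chemokine receptor that guides T cells into lymph nodes, was its highest member at 2632 ± 111, followed by the antiproliferative gene Btg1 at 2099 ± 271 and the transcription factor genes Ets1 (chromosome 9, 32636221 to 32757820) at 1633 ± 165 and Tcf7 (chromosome 11, 52252371 to 52283014) at 1541 ± 18.5. Actn1 at 65.1 ± 14.9 was the lowest member of the list.

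In the effector, memory and activation list, 13 of 24 members were detected at that level, with a list median of 4.82 ± 0.431 TPM (percentile 85.8 of random lists). Its highest members were the costimulatory receptor gene Icos at 259 ± 18.3, the early activation marker Cd69 at 146 ± 15.0, the transcriptional regulator Id2 at 92.2 ± 4.82 and Tnfrsf4 (OX40) at 90.8 ± 4.68. The granzyme genes Gzmb and Gzma had 0.327 ± 0.234 and 0.233 ± 0.404 and Ifng had 0.237 ± 0.210, whereas the perforin gene Prf1 had 55.7 ± 5.95; these 4 genes were singled out after their values were seen. On the log2(TPM + 1) scale the naive list median exceeded the effector list median by 7.26 ± 0.13. The difference was 7.29, 7.37 and 7.12 in libraries 1, 2 and 3. Its SD covers the spread between technical libraries and not the choice of list members. Leaving undetected members out brought the effector list median to 19.0 TPM and the difference to 5.48.

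**Figure D1:**
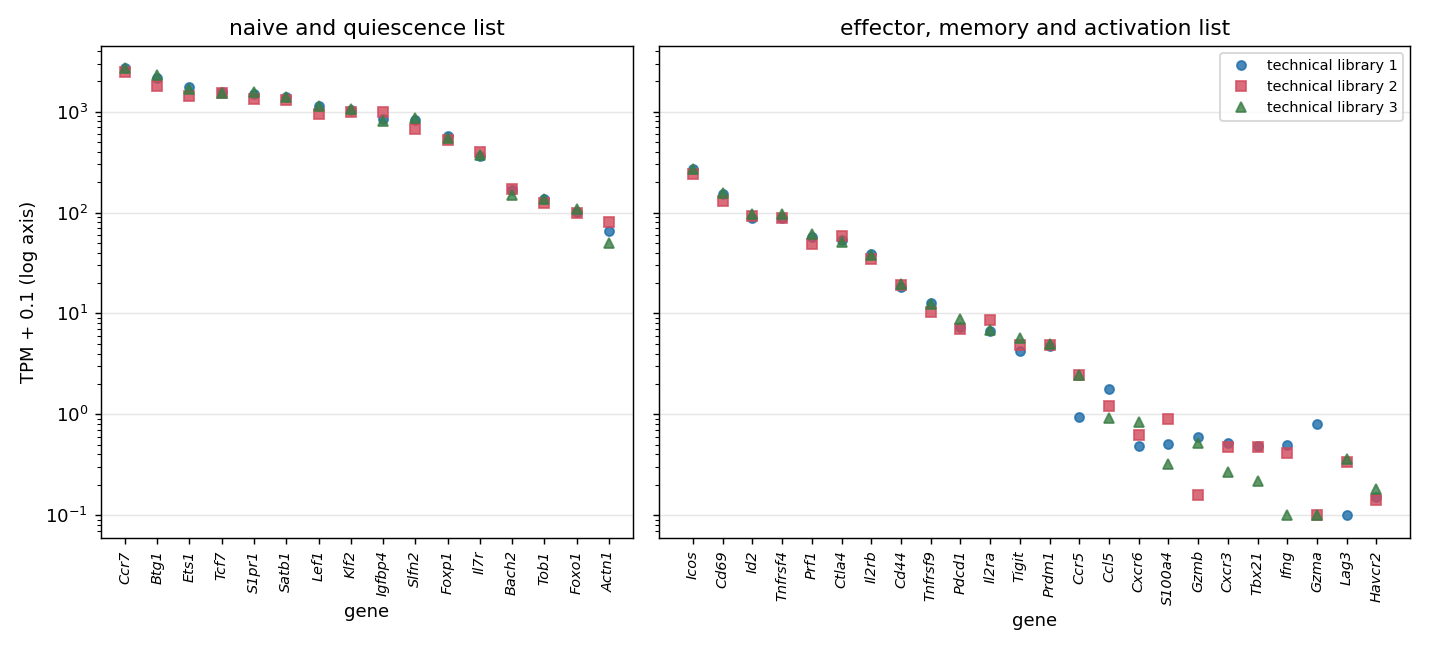
TPM + 0.1 on a log axis for members of the naive and quiescence list (left, with 1 member not drawn) and for each member of the effector, memory and activation list (right), with 1 point per technical library. Naive list members run from Ccr7 at a mean of 2632 TPM to Actn1 at 65.1 TPM, while the effector list runs from Icos at 259 TPM to Havcr2 at 0.0567 TPM.

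Ratios of single gene pairs compared genes of the naive state with effector genes. Here log2 ratios are of TPM + 0.1, mean ± SD. Cd44, an adhesion receptor that is high on antigen-experienced T cells, had 19.0 ± 0.705 TPM. Ccr7 exceeded Il2rb, a subunit of the interleukin-2 and interleukin-15 receptors (36.8 ± 2.15 TPM), by 6.16 ± 0.03, and Il7r (chromosome 15, 9505788 to 9530176; 377 ± 18.5 TPM), the receptor for the survival cytokine interleukin-7, exceeded the activation-induced Il2ra (7.28 ± 1.15 TPM) by 5.68 ± 0.15. Among transcription factors, Tcf7 exceeded Tbx21 (0.290 ± 0.147 TPM, 21 counts over the 3 libraries), which drives type 1 effector programs, by 12.03 ± 0.64; Lef1 (1085 ± 111 TPM) exceeded Id2 by 3.55 ± 0.17; and Bach2 (162 ± 11.6 TPM) exceeded Prdm1 (4.79 ± 0.121 TPM), which promotes effector differentiation, by 5.05 ± 0.13. Klf2 (1039.6 ± 33.1 TPM) exceeded Cd69 by 2.84 ± 0.11. The deposited counts on the older annotation gave smaller log2 ratios: 1.93 for Ccr7 to Il2rb, 4.90 for Il7r to Il2ra, 9.45 for Tcf7 to Tbx21, 3.07 for Lef1 to Id2, 3.79 for Bach2 to Prdm1 and 1.74 for Klf2 to Cd69. The older counts were a smaller part of the expected counts in the best-covered genes (median 23.7%) than in the least covered (55.4%). Ratios of abundant to rare genes are therefore lowered on them. Expected counts with no length correction gave 5.47, 5.57, 12.29, 4.70, 4.21 and 2.77 for the same pairs. Lef1 was below its relative Tcf7, at a log2 ratio of -0.51 ± 0.14, but the sign turned on the older counts, to 0.39. Over all 22 pairs, not all of which compare naive with effector genes, the first gene was the higher in 19. That number includes Bcl2 to Bcl2l11, at a log2 ratio of 0.05 ± 0.20, and is no measure of the naive state.

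T cell receptor genes and CD4 lineage genes were abundant, and the CD8 co-receptor genes were low. All 20 members of the T cell receptor and signalling list were detected, with a median of 628 ± 42.8 TPM (percentile 100). Trac, the constant region of the receptor α chain (chromosome 14, 54220521 to 54224206), had 2475 ± 249, and the β chain constant regions Trbc2 (chromosome 6, 41546730 to 41548352) and Trbc1 (chromosome 6, 41538218 to 41539881) had 2415 ± 53.9 and 1217 ± 37.2, a Trbc1 to Trbc2 log2 ratio of -0.99 ± 0.01 against -0.20 on the older counts; these paralogs can exchange reads. The proximal kinase gene Lck had 1182 ± 166 TPM. The constant region of the δ chain, Trdc, had 3.35 ± 0.151 TPM, so Trac exceeded it by 9.48 ± 0.08 on the log2 scale, or by 7.23 on expected counts with no length correction. All 6 members of the CD4 lineage list were detected (median 73.7 ± 8.54 TPM, percentile 99.4), led by Cd4 (chromosome 6, 124864692 to 124888221) at 444 ± 6.42, Cd40lg at 223 ± 6.79, St8sia6 at 104 ± 15.1 and Tox at 43.1 ± 1.98.

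Of the CD8 lineage list, 4 of 8 members were detected (median 1.85 ± 0.139 TPM, percentile 56.5), with Runx3 at 34.6 ± 2.12, Cd8b1 at 17 ± 0.235, Nkg7 at 2.60 ± 0.101 and Eomes at 2.49 ± 0.315. The CD8 co-receptor genes differed from each other: Cd8a (chromosome 6, 71373427 to 71379173) had 0.140 ± 0.0458 TPM, or 3 expected counts in each library, whereas Cd8b1 (chromosome 6, 71322788 to 71337494) had 730.5 counts in total. Cd4 exceeded Cd8a by 10.87 ± 0.29 on the log2 scale, and the ratio of length-scaled pooled counts was 3454 (exact Clopper-Pearson 95% interval 1819 to 7554). With so few Cd8a counts the log2 value depends on the pseudocount, being 8.61 with 1 and 11.58 with 0.01. For Cd8b1 the log2 difference was 4.70 ± 0.00455. On expected counts with no length correction Cd4 exceeded Cd8a by 11.80 and Cd8b1 by 5.69. Zbtb7b (9.85 ± 1.51 TPM), which encodes the CD4 lineage regulator ThPOK, was below Runx3, the CD8 lineage regulator, with a log2 ratio of -1.81 ± 0.29.

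Genes that define polarised helper cells were low, apart from a few regulators and receptors. In the T helper 1 list, 2 of 5 members were detected (median 0.320 ± 0.132 TPM, percentile 48.3), with Il18r1 at 24.5 ± 2.67, Il12rb2 at 1.37 ± 0.186, Cxcr3 at 0.320 ± 0.132 and Tbx21 at 0.290 ± 0.147. The T helper 2 list had 2 of 7 detected (median 0.0800 ± 0.0693 TPM, percentile 26.4): Gata3, which all CD4 T cells need, stood at 33.5 ± 1.19 and the chemokine receptor gene Ccr8 at 13.1 ± 1.06, while Il1rl1 had 0.230 ± 0.173 and Il4 0.0800 ± 0.139; without library 1 the list median was 0. No member of the T helper 17 list was detected in every library (0 of 7; median 0.0367 ± 0.0586 TPM, percentile 13.0), and its members Il17f, Ccr6 and Il22 had 0.567 ± 0.273, 0.320 ± 0.0872 and 0.0367 ± 0.0635. For T follicular helper genes, 4 of 6 were detected (median 5.16 ± 0.530 TPM, percentile 64.4), with Sh2d1a at 98.8 ± 7.96, Bcl6 at 19.4 ± 2.11, Pdcd1 at 7.64 ± 0.983 and Cxcr5 at 2.67 ± 0.0764. Posterior mean TPM gave higher medians for the T helper 1, 2 and 17 lists, of 0.553, 0.623 and 0.270. For the T follicular helper list it gave a lower one, of 4.78.

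Regulatory T cell genes were present at moderate levels, with 11 of 13 members detected (median 10.6 ± 1.94 TPM, percentile 88.7). Tnfrsf18 (GITR) had 252 ± 23.9, Tnfrsf4 90.8 ± 4.68, Ctla4 54.1 ± 3.54 and Capg 44.4 ± 3.23. Foxp3 (chromosome X, 7573644 to 7595245), the lineage factor of regulatory T cells, had 18.9 ± 1.81 TPM, and Foxp1 (548 ± 24.5 TPM), a quiescence factor, exceeded it by 4.86 ± 0.19 on the log2 scale, or 3.69 on the older counts and 4.21 with no length correction. Tnfrsf4, Ctla4 and Il2ra also belong to the effector list. Unconventional T cell genes were low (2 of 7 detected, median 0.240 ± 0.105 TPM, percentile 44.8): the highest were Trdc, Tcrg-C1 at 1.48 ± 0.329, Sox13 at 0.460 ± 0.320 and Tcrg-C2 at 0.240 ± 0.251. The list median was 0.110 TPM without library 3 and 0.360 without library 1.

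Few genes of CD4 CD8 double-positive thymocytes were present. Of that list, 3 of 8 members were detected (median 0.650 ± 0.0492 TPM, percentile 45.8), with Cd1d1 at 84.6 ± 3.73, Cd8b1 at 17 ± 0.235, Dntt at 7.83 ± 0.890 and Arpp21 at 1.09 ± 0.175; with posterior mean TPM the list median was 2.10. In the list for immature CD4 thymocytes or recent thymic emigrants, 7 of 9 were detected (median 20.5 ± 2.02 TPM, percentile 92.8), led by Itm2a at 284 ± 37.4, Cd69, Nr4a3 at 54.7 ± 18.1 and Tox. S1pr1 (1461 ± 113 TPM; chromosome 3, 115710433 to 115715072), the receptor with which mature thymocytes leave the thymus, exceeded Cd24a (2.72 ± 0.554 TPM), a marker of immature thymocytes, by 9.03 ± 0.38 on the log2 scale, or by 9.83 with no length correction.

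Most markers of other blood and tissue cells did not reach 1 TPM in every library, with Ighm and Pecam1 as the main exceptions. Some others were low but well above the limit of 3 counts, among them Klrd1 with 263 and Cd74 with 359 counts in total. In the B cell list, 3 of 14 members were detected (median 0.288 ± 0.0340 TPM, percentile 39.9). Ighm, the immunoglobulin μ constant region (chromosome 12, 113418558 to 113422730), had 374 ± 56.3 TPM, while Cd74 had 10.2 ± 2.10, Cd79a 2.06 ± 0.632 and H2-Ab1 1.30 ± 0.488. Of the stroma, epithelium and endothelium list, 2 of 14 were detected (median 0.0417 ± 0.0104 TPM, percentile 6.75): the adhesion molecule gene Pecam1 (CD31) had 140.3 ± 7.91, Epcam 3.30 ± 0.593, Dcn 0.287 ± 0.253 and Aire 0.207 ± 0.191. Natural killer genes numbered 2 of 8 detected (median 0.217 ± 0.231 TPM, percentile 34.4), with Klrd1 at 12.1 ± 2.83, Eomes at 2.49 ± 0.315, Tyrobp at 0.493 ± 0.565 and Gzma at 0.233 ± 0.404. Among myeloid genes 2 of 14 were detected (median 0.130 ± 0.176 TPM, percentile 26.2), the highest being Itgam at 1.63 ± 0.0651, Fcgr3 at 1.41 ± 0.409, Cd68 at 1.01 ± 0.682 and Tyrobp. Dendritic cell genes reached 1 TPM in 0 of 7 cases (median 0.0600 ± 0.0153 TPM, percentile 21.4), with Zbtb46, Xcr1, Cd209a and Flt3 at 0.333 ± 0.0503, 0.193 ± 0.0751, 0.0867 ± 0.0306 and 0.0600 ± 0.0361. Erythroid and platelet genes numbered 1 of 10 (median 0.183 ± 0.0236 TPM, percentile 32.7), with Hbb-bs at 1.18 ± 0.312, Itga2b at 0.777 ± 0.739, Hba-a2 at 0.337 ± 0.187 and Pf4 at 0.260 ± 0.450; the haemoglobin genes have near-identical copies. Where members are near 0 the median of the means can lie outside the per-library medians, which for this list were 0.0650, 0.1 and 0.110 TPM in libraries 1, 2 and 3. Without library 3 the median was 0.0850 TPM for this list and 0.05 for the myeloid list. Posterior mean TPM gave higher medians, of 1.55 for the B cell list, 0.548 natural killer, 0.627 myeloid, 0.470 dendritic, 0.558 erythroid and 0.568 stroma.

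Cd3e (761 ± 28.8 TPM), part of the T cell receptor complex, exceeded the B cell gene Cd79a by 8.50 ± 0.41, or 5.88 on the older counts, and the haemoglobin gene Hbb-bs by 9.24 ± 0.31 on the log2 scale. For Hbb-bs the value was 11.21 on expected counts with no length correction. On the older counts Hbb-bs had 0 counts, so the value of 11.16 there is set by the pseudocount and is no measured ratio. Against the macrophage lysozyme gene Lyz2, with 1 count over the 3 libraries, the pooled ratio was 25343 (exact Clopper-Pearson 95% interval 4548 to 1001010). Against the natural killer gene Ncr1, also with 1 count, it was 28510.5 (interval 5117 to 1126140). The labels state a male animal. In the sex-linked list 4 of 5 members were detected (median 33.2 ± 2.89 TPM, percentile 92.8), with Eif2s3y at 124 ± 6.24, Ddx3y at 115 ± 7.44, Uty at 33.2 ± 2.89 and Kdm5d at 22.2 ± 0.437. Xist, the X-inactivation RNA, had 2 counts over the 3 libraries, and Ddx3y to Xist had a pooled ratio of 17308 (exact Clopper-Pearson 95% interval 4790.1 to 142933).

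**Figure D2:**
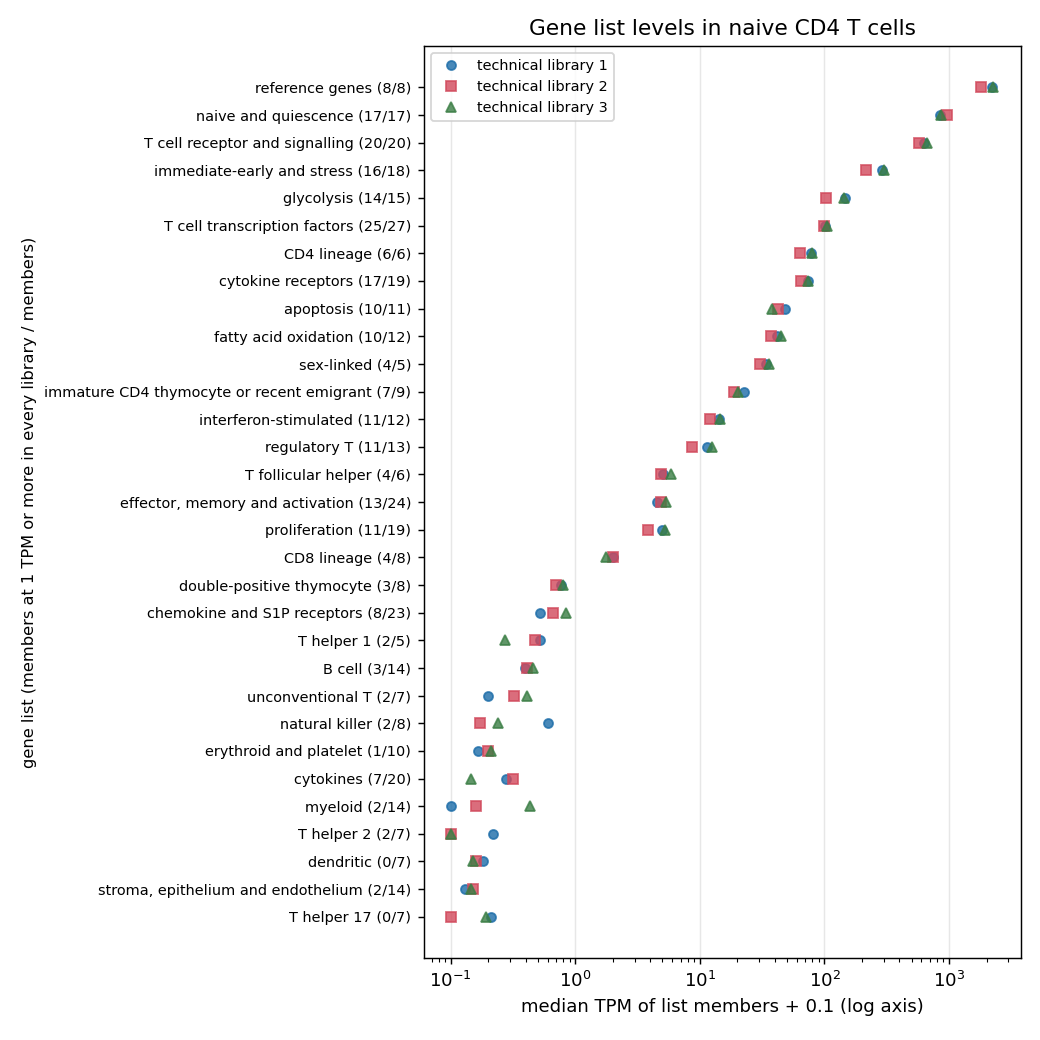
Median TPM over list members, plus 0.1, on a log axis for each of the 31 gene lists, with 1 point per technical library; each label gives the number of members at 1 TPM or more in every library and the number of members. Lists of T cell receptor (628 TPM) and naive genes (884 TPM) lie far to the right of the B cell, natural killer, myeloid, dendritic, erythroid and stromal lists, which have medians under 1 TPM in the values drawn; with posterior mean TPM the B cell list median was 1.55.

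In the proliferation list 11 of 19 members were detected (median 4.56 ± 0.766 TPM, percentile 82.5), led by Pcna at 155 ± 9.80, Stmn1 at 91.1 ± 15.8, Mcm7 at 91.0 ± 3.62 and Mcm4 at 90.1 ± 8.58. Mki67, which is expressed in cycling cells, was the lowest member at 0.137 ± 0.0666. The 8 members under the detection level were Mki67, Cdk1, Ccnb1, Ccnb2, Ccna2, Birc5, Aurkb and Bub1. Immediate-early and stress genes were abundant, with 16 of 18 detected, a median of 268 ± 45.4 TPM and a percentile of 100. The AP-1 genes Junb (chromosome 8, 84974484 to 84978718) and Jund had 2883 ± 568 and 1028 ± 221, and the heat shock genes Hspa1b and Hsp90aa1 had 763 ± 115 and 460.5 ± 110.5; Hspa1b is nearly identical to Hspa1a, so its value is uncertain. The list median was 217 TPM in library 2 against 289.7 and 300.5 in libraries 1 and 3. Of the interferon-stimulated genes 11 of 12 were detected (median 13.5 ± 1.44 TPM, percentile 91.1), with Ifi27l2a at 153 ± 9.61, Irf7 at 95.9 ± 11.1 and Bst2 at 60.1 ± 2.55.

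Receptors for cytokines were widely expressed, while most cytokines were not. Of the cytokine receptor genes 17 of 19 were detected (median 70.9 ± 4.96 TPM, percentile 100), led by the common γ chain Il2rg at 1172 ± 162, Ifngr1 at 1171 ± 114, Il4ra at 749 ± 77.9 and Il21r at 609 ± 65.7. Only 8 of 23 chemokine and sphingosine-1-phosphate receptor genes reached 1 TPM in every library (median 0.550 ± 0.160 TPM, percentile 55.9): after Ccr7 and S1pr1 came Cxcr4 at 97.5 ± 19.7 and S1pr4 at 76.8 ± 2.60. Among cytokine genes 7 of 20 were detected (median 0.138 ± 0.0889 TPM, percentile 26.2), with lymphotoxin β (Ltb) at 762 ± 137, Il16 at 335 ± 28.8, Flt3l at 206 ± 8.12 and Tgfb1 at 75.6 ± 14.3. Posterior mean TPM gave higher medians for the cytokine list, 0.415, and the chemokine and sphingosine-1-phosphate receptor list, 0.943. For the cytokine receptor list it gave a lower one, 61.3. The T cell transcription factor list had 25 of 27 detected (median 103 ± 2.91 TPM, percentile 100), headed by Ets1, Tcf7, Satb1 (chromosome 17, 51736187 to 51833290) at 1361 ± 54.3 and Lef1 (chromosome 3, 131110471 to 131224356).

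Survival genes were led by Mcl1. In the apoptosis list 10 of 11 members were detected (median 44.6 ± 5.20 TPM, percentile 99.3), with Mcl1 at 555 ± 17.5, Bax at 179 ± 18.1, Bcl2 (chromosome 1, 106538178 to 106714274) at 149 ± 9.50 and Bcl2l11 (chromosome 2, 128126038 to 128162547) at 144 ± 11.02. Bcl2 exceeded its antiapoptotic relative Bcl2l1 (10.5 ± 0.796 TPM) by 3.81 ± 0.03 on the log2 scale, or by 5.05 with no length correction. Bcl2 and the proapoptotic Bcl2l11 (BIM) were indistinguishable within the technical spread, at a log2 ratio of 0.05 ± 0.20, and without library 3 the sign turned, to -0.04. This rests on the length scaling of TPM, since Bcl2 was the higher by 1.03 on expected counts with no length correction and by 0.92 on the older counts. Glycolysis genes numbered 14 of 15 detected (median 134 ± 24.3 TPM, percentile 100), with Ldha at 834 ± 73.0, Eno1 at 809.9 ± 115, Pkm at 653 ± 84.5 and Aldoa at 471 ± 51.5, while the inducible hexokinase Hk2 had 0.477 ± 0.240. Fatty acid oxidation genes numbered 10 of 12 (median 41.1 ± 3.89 TPM, percentile 99.4), with Hadhb at 194 ± 16.1, Acadvl at 91.9 ± 19.5, Acaa2 at 85.5 ± 7.51 and Hadha at 67.2 ± 8.56. All 8 reference genes were detected (median 2088 ± 258 TPM, percentile 100), with B2m at 4289 ± 285, Eef1a1 at 4006 ± 1248, Ppia at 3294 ± 170.3 and Actb at 2352 ± 299.

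Transcript shares were estimated for 16 T cell genes, and in 8 of them a single transcript held at least 50% of the gene's TPM. Among these the share of the most abundant transcript was 89.97% ± 2.17 for Cd4, 73.4% ± 16.3 for Zbtb7b, 73.3% ± 1.25 for Tcf7, 70.8% ± 0.930 for Il7r, 67.4% ± 3.47 for Bcl11b, 62.8% ± 0.583 for Ets1 and 59.5% ± 6.55 for Cd44. In the genes under 50% it was 46.7% ± 3.08 (Ptprc, the CD45 gene), 44.7% ± 2.06 (Bach2), 41.0% ± 1.68 (Ikzf1), 38.5% ± 3.07 (Lef1), 35.2% ± 3.22 (Satb1), 30.6% ± 2.87 (Runx1), 30.5% ± 0.704 (Bcl2l11) and 21.9% ± 1.49 (Foxp1, with 31 annotated transcripts). The most abundant Il7r transcript had 3540 bases and was accompanied by a 1548-base transcript annotated as noncoding at 25.2% ± 1.11. In Tcf7 the 2471-base transcript was the major form and the 1742-base form held 26.7% ± 1.25. The Zbtb7b share varied most between libraries, from 56.8% in library 1 to 89.4% in library 3. With posterior mean percents the Zbtb7b share was 39.1% and the number of genes at 50% or more was 7. With shares of expected counts it was 10: Bach2 at 68.7%, Ptprc at 63.8%, Bcl2l11 at 55.4% and Ikzf1 at 51.0% then lay above 50%, while Bcl11b at 47.6% and Cd44 at 47.0% lay below it. Shares from short reads rest on a statistical model of read assignment.

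The technical libraries differed by more than independent counting of reads would give, and library 2 stood apart from the others. Of 13090 genes with a mean of at least 10 counts, 5238 (40.0%) differed between the 3 libraries by a chi-square test of homogeneity at a Benjamini-Hochberg adjusted threshold of 0.05; the test compares these libraries, not conditions. It treats each read as an independent molecule, so PCR copies add to the number. On the counts of the older annotation 1895 of 10013 genes (18.9%) differed, and with no count minimum 4881 of 31508 (15.5%). Without library 2 the number was 1903, without library 1 it was 4875 and without library 3 it was 3615. Among the 4542 such genes with a mean of at least 100 counts, library 2 was the farthest from the other libraries in 2777, library 3 in 1327 and library 1 in 438. The differences were mostly small: over genes with a mean of at least 100 counts, the median fold between libraries was 1.06 for libraries 1 and 3, 1.09 for 1 and 2 and 1.12 for 2 and 3, and 19, 60 and 137 of 9135 genes differed by over 2-fold in these pairs. The mean chi-square per gene with 1 degree of freedom was 5.89, 25.7 and 38.8 for the same pairs. The median was far lower, at 1.15, 1.98 and 2.83, against 0.455 for counting noise alone. By either measure no pair agreed within sampling noise, and each library was counted once.

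Of the 10 genes with the largest range between libraries, those other than C130083A15Rik had expected counts that were not whole in at least 1 library, so reads were split with other entries and their values are uncertain. Hist1h2ao (chromosome 13, 21810465 to 21810944) had 0 counts in library 1 against 265 in library 3, and its neighbour Hist1h2ap (chromosome 13, 21833026 to 21833507) had 264 in library 2 against 0 in library 3. With the library at 0 set to 3 counts, the ranges were 6.23 and 6.44 on the log2 scale. These values allow for counting error only and not for the split of reads, so they are no lower limits. In libraries 1, 2 and 3 Hist1h2ao had 0, 54.05 and 264.55 counts and Hist1h2ap 194.17, 264.07 and 0. Each was at 0 where the other was not, and assignment of reads between the neighbours was not tested. Gm28661, a pseudogene entry on chromosome 1, had 236 TMM-scaled CPM (counts scaled to library size) in library 2, 107 in library 3 and 3.22 in library 1. Gm10800, Gm10801, C130083A15Rik and the 7S RNA entry Rn7s1 were highest in library 2, at 93.8, 15.4, 22.0 and 32.4 CPM against 11.6, 1.81, 4.09 and 8.11 in library 1 and 21.7, 4.03, 3.29 and 5.16 in library 3. B430305J03Rik and Gm20721 were lowest in library 2, at 3.36 and 5.10 against 16.0 and 36.8 in library 1, and Gm20481 was lowest in library 3, at 0.908 against 10.98 in library 2.

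**Figure D3:**
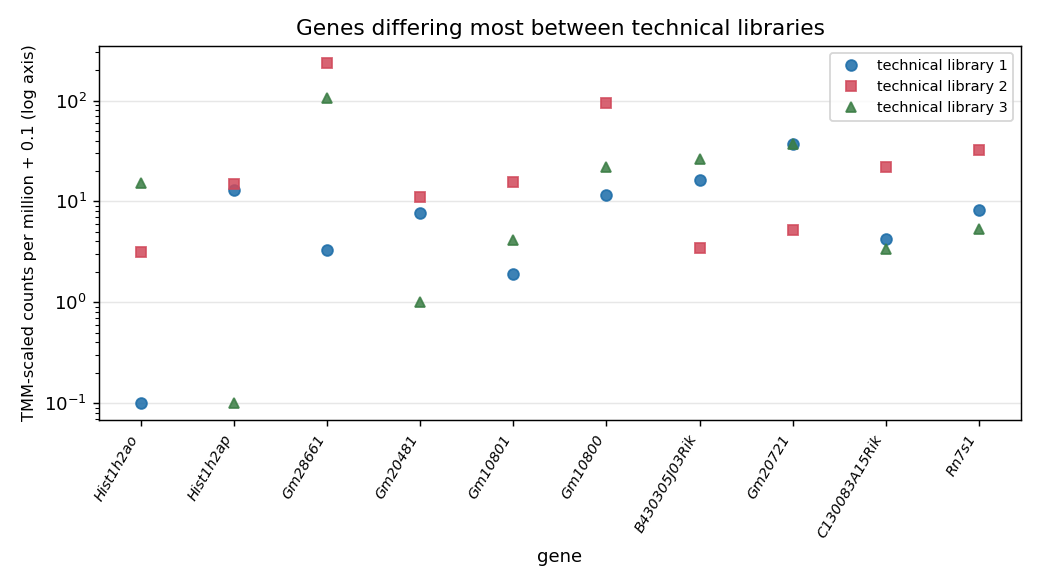
TMM-scaled CPM, plus 0.1, on a log axis for the 10 genes with the largest ratio of highest to lowest library among genes past the chi-square threshold with a mean of at least 100 counts, with 1 point per technical library. Gm28661 spans 3.22 in library 1 to 236 in library 2, and the points at 0.1 are libraries with 0 counts.

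The technical coefficient of variation, the square root of edgeR's common dispersion, was 12.7% over the 3 libraries, against 8.47% on the older counts and 5.66% as DESeq2's median gene-wise value. In simulation a few strongly differing genes raised the edgeR value, and the DESeq2 median fell below the truth. It was 7.20% for libraries 1 and 3 alone, against 12.5% for 1 and 2 and 16.1% for 2 and 3. Correlations of log2(TPM + 1) were taken across 55536 genes, which are not independent replicates. Libraries 1 and 3 had a Pearson r of 0.989 and a Spearman rho of 0.832. The values were 0.988 and 0.829 for libraries 1 and 2 and 0.987 and 0.827 for 2 and 3. Over the 13118 genes of mean TPM of at least 1, the Spearman rho was 0.978, 0.974 and 0.974 for the same pairs. Among named T cell genes, Cd4 had 439, 442 and 451 TPM and Ccr7 2695, 2504 and 2695 TPM in libraries 1, 2 and 3. Larger shifts were seen for Eef1a1, a translation elongation factor gene, with 3383, 5442 and 3191, and for Junb, with 3153, 2230.0 and 3266; these genes were singled out after their values were seen.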

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

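The tests on duplicate reads, on reads shared between genes, on GC content and on length had their bounds set before their results were seen; the test on B cells was chosen only after the result was seen. The design names no second group, so the explanations tested were technical, RNA from other cells among them, and no biological difference between groups was tested.

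Signal was present in entries outside the genes analysed. The phiX174 entry, a bacteriophage genome used as a sequencing control, held 0.240%, 0.190% and 0.319% of expected counts in libraries 1, 2 and 3, far above the 3 counts that a count of 0 allows. Short entries with numeric identifiers held 1010.1, 1687 and 1073 expected counts in the same libraries. The ERCC spike-in entries held 0 counts in every library.

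Library 2 lay apart from libraries 1 and 3, with a mean chi-square of 64.6 per gene against the others over 9129 genes. Its log2 ratio to the other libraries followed neither transcript GC content (Spearman rho across genes 0.0188) nor transcript length (rho 0.0412), both under the bound of 0.1, and removing a cubic trend in GC left 97.3% of the chi-square, whereas the ratio of library 3 to library 1 had a rho of -0.182 with GC content. Duplicate reads in the expected counts stay open. The ratio had a Spearman rho of 0.867 across genes with that in the counts on the older annotation, past the bound set beforehand against this explanation. The rule that leaves this test undecided was made after its value was seen. Both tables count reads of the same libraries, and the test needs duplicates to be removed from the older counts, which is itself left open below. Library 2 also had the highest share of ribosomal RNA entries, 1.11% of expected counts against 0.282% and 0.249%, and the highest share of ribosomal protein genes. A difference in RNA handling or library preparation remains open and was not tested.

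The whole-number counts on the older annotation summed to 34.8%, 31.9% and 32.6% of the expected counts in libraries 1, 2 and 3. Loss of reads that were split between genes is argued against as the whole cause. The 4447 genes whose expected counts were exactly whole in every library had a median ratio of 0.542, under the bound of 0.7. Whole counts do not show that no reads were shared, since a read that matches several places can be assigned wholly to 1 entry. Loss of such reads was not tested. Removal of duplicate reads stays open, because the ratio fell with expected counts per base at a Spearman rho of -0.293 across genes, just short of the bound of -0.3 that had been set for it. The fall was seen in well-covered genes. In 10 equal groups of genes ordered by rising coverage, the median was 55.4% in group 1, 57.7% in group 6 and 23.7% in group 10. Values for which no bound was set go with duplicate removal. Older counts per base peaked at 4.31, 4.56 and 4.70 in libraries 1, 2 and 3, against 81.9, 106.3 and 93.6 for expected counts. Genes over 2 counts per base numbered 17, 20 and 19 on the older counts, against 678, 853 and 856 on expected counts. Duplicate removal alone would still leave the low value in poorly covered genes unaccounted for.

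Ighm stood at 374 ± 56.3 TPM in a sample of CD4 T cells. B cells are argued against as its source, since the median of the 13 other B cell markers was 0.0741% of the Ighm level and the highest of them, Cd74, was 2.74% of it. The 2 annotated Ighm transcripts held 54.9% ± 1.78 and 45.1% ± 1.78 of its TPM. Its source stays open.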

How the results depend on the processing

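Use of the counts on the older annotation was chosen after seeing the data; the other alternatives were set before. The number of genes differing between libraries lay within 1.5 times 5238 under library totals, DESeq2 size factors, other count minimums, a threshold of 0.01, posterior mean counts and a deviance test. Leaving out each library gave 1903 to 4875, lowest without library 2. The older counts gave 1895 of 10013 genes, and for pairs 1745 without library 1, 503 without library 2 and 1200 without library 3; these tables hold fewer reads. The coefficient of variation ran from 7.20% to 16.1% with each library left out, was 5.66% as DESeq2's median, which fell below the truth in simulation, and 8.47% on the older counts. Genes detected rose to 18019 with posterior mean TPM. The mean Pearson r was 0.966 with a pseudocount of 0.1 and 0.969 over genes of mean TPM of at least 1, and 0.987 to 0.989 with each library left out. The naive list median was 764 TPM with posterior means and 1153 after rescaling over protein-coding genes; the effector list median was 4.33 and 6.25, and 19.0 over members of mean TPM of at least 1. Their log2 difference was 7.50 with a pseudocount of 0.1, 5.48 over such members and 6.39 with means. The 10 highest genes held 4.51% of expected counts and 5.36% of posterior mean TPM. Signs turned in the Bcl2 to Bcl2l11 ratio, which with each library left out ran from -0.0372 without library 3 to 0.157 without library 2, and in the Lef1 to Tcf7 ratio, to 0.389 on the older counts, whose cause was not tested; expected counts with no length correction kept the sign, at -0.34. Across all lists 76 of 184 alternatives moved the median by more than the technical SD, as did 59 of 174 for pair ratios (besides the 2 whose sign turned), 16 of 80 for isoform shares and 17 of 55 for composition. Some moves of list medians follow from the alternative itself. Rescaling over protein-coding genes multiplies all TPM of a library by the same factor. Leaving out members of mean TPM under 1 can only raise a median or keep it. For the other moves, except where given above, the cause was not tested. No median over members of mean TPM of at least 1 exists for the T helper 17 and dendritic lists. The exact multinomial test was not run, since each of the 10 genes named for library differences had a mean of at least 100 counts.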

Other observations

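The gene families and Prf1 here were chosen after their values were seen. All 8 Gimap genes, which encode GTPases that support lymphocyte survival, reached 100 TPM in every library and summed to 6173 ± 375 TPM, led by Gimap6 (chromosome 6, 48701582 to 48708225) at 2262 ± 161, Gimap3 at 1619 ± 97.6 and Gimap4 at 1074 ± 82.6. In the Ms4a family, whose member Ms4a1 encodes the B cell protein CD20, Ms4a4b and Ms4a6b had 1360.4 ± 77.5 and 551 ± 37.7 TPM while Ms4a1 had 0.130 ± 0.0608. Of the Klf transcription factors 10 of 17 were detected, with Klf6 at 842 ± 113, Klf3 at 599 ± 53.0 and Klf13 at 468 ± 62.2 beside Klf2. Among integrin genes 12 of 26 were detected, and the gut-homing subunit Itgb7 was the highest at 779 ± 46.3, above the leukocyte subunit Itgb2 at 335 ± 31.1, Itga6 at 169.5 ± 12.6 and Itgal at 135 ± 4.71. Ly6e at 1024 ± 20.9 and Ly6c1 at 288 ± 23.6 led the Ly6 family, and Slfn1 at 156 ± 8.66 followed Slfn2 in the Schlafen family.

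All 22 β chain variable segments counted were detected at 1 TPM or more in every library. Trbv13-2 held 12.7% ± 0.544 of Trbv TPM, Trbv31 8.66% ± 0.179, Trbv16 7.52% ± 0.429 and Trbv3 7.51% ± 0.458; related segments can exchange reads. Of the classical and nonclassical MHC class I genes 11 of 24 were detected, and after H2-K1 and H2-D1 came H2-Q7 at 1229.8 ± 128 and H2-Q6 at 392 ± 13.0, near-identical genes whose split is uncertain. Prf1, the perforin gene, had 55.7 ± 5.95 TPM although Gzma and Gzmb were near 0, and 83.9% ± 5.05 of it was assigned to the transcript ENSMUST00000219375.1.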
